A study of Rattus norvegicus with 300 samples.

How the data were processed

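The deposited table held raw read counts for 17337 gene symbols in 300 libraries, and all its columns were matched to labelled samples, leaving 0 unmatched. Per the submitters' processing notes, reads were aligned to rn6 with STAR and counted with HTSeq after FastQC; their versions and settings are not given in the sources used here. The authors made the libraries with a stranded total RNA kit from punches of frozen sections, pooled by region, and sequenced them as paired ends. The counts were checked to be whole numbers without normalization. Of the symbols, 14821 were found as current rat symbols and 2125 as older ones. How many rats went into each pool is not given in the sources used here, so n counts libraries or treatment replicates, not rats. Labels named 10 regions, 6 treatments and 5 replicates per group, making 60 groups.

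Total counts per library ran from 198260 to 18310687, with a median of 9232563. Precision rests on the spread between the 5 replicates: over 9663 genes above 5 CPM, the median SD between treatment replicates was 0.0842 on the log2 scale, and 71 genes had an SD above 0.3. Labels were checked by comparing each library with the mean profile of each region in the other treatments, and by Y-linked genes, since the rats were male. Eif2s3y was counted in 300 libraries and Ddx3y in 223. All 600 pairs of libraries within groups were checked for repeats of the same library; the lowest chi-square per degree of freedom was 1.36, in Desipramine NACShell. No library was left out, moved or relabelled.

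Each drug was compared with Control, Probiotics with Maltodextrin, and Maltodextrin with Control, making 5 comparisons. In each region, the 30 libraries were fitted together in edgeR (4.0.16, R 4.3.3) with TMM normalization, the filterByExpr filter and the quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg over the genes of a comparison. A gene was called at an adjusted p under 0.05. For all regions together, counts of the 10 regions were summed within each treatment replicate, giving 30 sums, because regions of 1 replicate are not independent samples. A gene-wise offset took up differences in depth between regions. Regions weigh in this sum by their counts of a gene, so its fold change mostly follows the regions where it is abundant. The 9 terms for a treatment effect that differs between regions were tested on the 100 libraries of the groups compared, with the treatment replicate and the region in the model. The 6 differences between effects were tested as contrasts of the all-region fit.

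CPM means with SD were computed from raw totals. Fold changes come from TMM-normalised fits, so the ratio of CPM means and the fitted change can differ in size, and for small changes in sign. Slc6a4 in Raphe stood at 124 CPM in Control and 172 CPM in FT at a log2 change of 0.12, and Tph2 at 751 CPM in Control and 760 CPM in Desipramine at a log2 change of -0.26.

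Relations of Oxt and Avp between regions were tested on the log2 of CPM plus 0.05 by 100000 permutations within treatments, two-sided. The design listed 33 gene lists, and lists with at least 5 tested members were tested with camera in limma (3.58.1), which compares a list with the other genes. It used a preset correlation of 0.01 between genes and log2 CPM with a prior count of 2, for all regions on region-centred means and for single regions. The mitochondrially encoded list had 0 members in the table and was not tested. Overlaps between comparisons were set beside independent lists, 20 simulations of unchanged groups against the same controls, and the median over the 10 ways to split the control replicates into 2 and 3.

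Genes to name were chosen by a rule fixed before the data were examined, as were the comparisons, tests, gene lists and most of the alternatives. For each comparison the rule took, among genes called over all regions with a mean log2 CPM over 0, an ordinary symbol and the same sign in at least 8 of 10 regions, the 6 with the highest positive and the 6 with the lowest negative change. It took, in the 3 regions with most calls, the 3 higher and 3 lower genes with the smallest adjusted p. It added Slc6a4 and Tph2 in Raphe, Slc6a2, Th and Dbh in LConly, Bdnf in dorDG and venDG, and Fkbp5 and Fos over all regions. For each called list it took up to 4 members with the smallest p, and across comparisons up to 10 genes called in the same direction in several of them. Ttr, Mbp, Slc17a7 and other genes given by their CPM in single groups were chosen after their values were seen. A few genes that the rule took are not reported here.

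The methods were tested on simulated data with 200 changed genes in FT against Control. The all-region test recovered 97.0, 100 and 100% of genes changed 1.2-fold, 1.5-fold and 2-fold and called 0.0597% of unchanged ones. In PLC alone it recovered 26.9, 92.5 and 98.5% and called 0.0425% of unchanged genes. The test for differences between regions recovered 4.48, 68.7 and 84.8% of genes changed in PLC only and called 0.204% of unchanged genes. In camera, the limma test, a changed list had a p of 1.44e-150 and an unchanged list a p of 0.641.

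Alternatives were DESeq2's RLE size factors, no filter, DESeq2 (1.42.0), a fit on only the groups compared, the replicate number as a block, Control and Maltodextrin pooled as the control of the drugs, Control as the control of Probiotics, surrogate variables (sva 3.50.0), limma on mean log2 CPM or with trend, an unadjusted p under 0.01, an estimated correlation, a prior count of 0.5, and leaving out replicates. Chosen after seeing the data were fits without the 4 libraries under 1000000 counts, without ILC and LConly, and with only CGC, mPOA, NACShell, PLC and Raphe, and with the main axis of variation within groups as a covariate. Gene length and GC content were not used here, since no reference genome was at hand.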

Results

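RNA was counted in 300 libraries of punched brain tissue from male Long Evans rats, which were 60 days old and took 1 of 6 treatments in their drinking water for 3 weeks. Control rats drank water, and Maltodextrin rats drank the carrier sugar at 10 g/L. The other groups took FT at 13 mg/kg/day, Bupropion at 15 mg/kg/day, Desipramine at 7.5 mg/kg/day, or Probiotics. The labels write FT without spelling it out; fluoxetine is the drug of the protocol that no other group name takes. They give the probiotic dose in forms that disagree, so no dose is printed. Bupropion and desipramine are antidepressants that act on noradrenaline or dopamine uptake, and fluoxetine is one that acts on serotonin uptake. Tissue came from 10 brain regions, named here as the labels abbreviate them: BLA, CGC, dorDG, ILC, LConly, mPOA, NACShell, PLC, Raphe and venDG. Each of the 60 combinations of region and treatment held 5 libraries. Because punches were pooled before extraction, p-values measure only the spread between these libraries. Counts were given for 17337 gene symbols, and total counts per library ran from 198260 to 18310687 (median 9232563). The libraries below 1000000 counts were 4 from Desipramine, with 198260 in BLA replicate 3, 571357 in NACShell replicate 1, 825020 in dorDG replicate 1 and 841455 in CGC replicate 1.

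Marker genes placed most libraries in the region of their label. In Control, Dbh, the enzyme that makes noradrenaline, stood at 140 ± 12.8 CPM (counts scaled to a library total of 1000000; mean ± SD, n = 5) in LConly, and Tph2, the first enzyme of brain serotonin synthesis, at 751 ± 25.4 CPM in Raphe. Oxt, which encodes the hormone oxytocin, reached 1018 ± 119 CPM in mPOA, Drd1, a dopamine receptor of striatal neurons, 238 ± 5.99 CPM in NACShell, and Prox1, a transcription factor of dentate granule cells, 80.4 ± 8.28 CPM in dorDG. By its whole profile, 269 of 300 libraries lay nearest to the other treatments' mean of their own region. The FT libraries labelled ILC and LConly carried each other's markers. Dbh stood at 255 ± 39.4 CPM in the FT libraries labelled ILC and at 0.65 ± 0.3 CPM in those labelled LConly, against 62.5 to 276 CPM in LConly of the other groups. Tbr1, a transcription factor of cortical excitatory neurons, stood at 0.485 ± 0.354 CPM in the FT libraries labelled ILC and at 18.1 ± 4 CPM in those labelled LConly. No library was moved, and results of FT in these regions are those of the libraries so labelled.

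Several other groups stood apart in single regions. Cd74, the invariant chain of MHC class II molecules, was at 536 ± 48.5 CPM in BLA and 567 ± 13.8 CPM in venDG of Control, while the other treatments' means reached no more than 38.8 CPM in those regions. Cxcl13, a chemokine that attracts B cells, was at 109 ± 7.68 CPM in Control venDG. Ttr, the thyroid hormone carrier made by choroid plexus, was at 7956 ± 955 CPM in BLA and 5762 ± 721 CPM in dorDG of FT, against 29.8 and 31.7 CPM in Control. In LConly it was at 6222 ± 404 CPM in Maltodextrin and 16980 ± 602 CPM in Probiotics, against 39.6 CPM in Control. Mbp, a main protein of myelin, was at 597 ± 39.6 CPM in dorDG of Probiotics and at 5799 to 9393 CPM in dorDG of the other groups. Slc17a7, the glutamate transporter of cortical and hippocampal excitatory neurons, was at 23.4 ± 2.48 CPM in ILC of Control and at 28.6 ± 3.3 CPM in dorDG of Probiotics, against 274 ± 10.6 and 444 ± 12.8 CPM in the same regions of Maltodextrin. Counts over fewer regions below leave out BLA, dorDG, ILC, LConly and venDG for this reason, a choice made after these values were seen. The regions kept were not free of such groups: mPOA of FT stood apart in Pomc and NACShell of FT in Oxt, as given below.

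**Figure D1:**
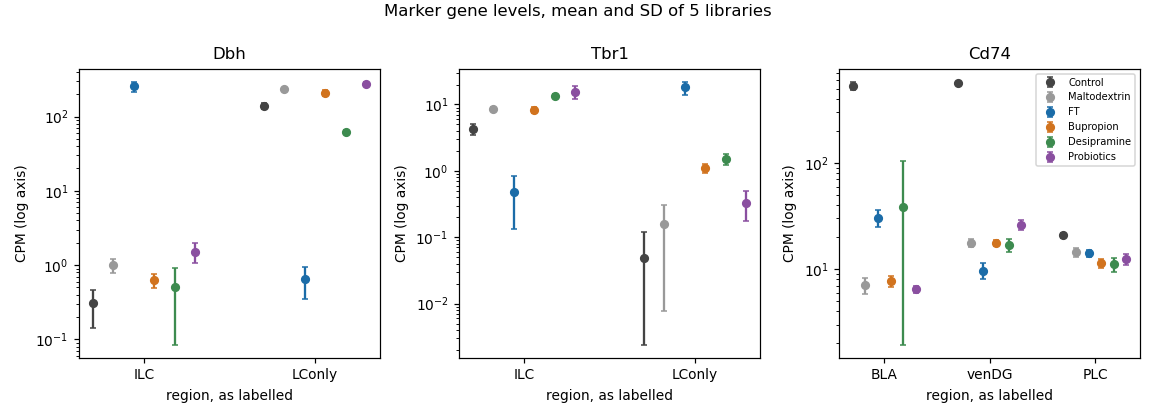
CPM (log axis) of Dbh and Tbr1 in ILC and LConly and of Cd74 in BLA, venDG and PLC, as mean and SD of 5 libraries for each of the 6 treatments, with lower bars shortened where they would reach 0. Dbh lies at 255 CPM in the FT libraries labelled ILC and at 0.65 CPM in those labelled LConly, and Cd74 at 536 and 567 CPM in BLA and venDG of Control.

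Oxt outside mPOA followed its level in mPOA. Over the 30 treatment replicates, centred within treatments on the log2 scale, the median of the 9 other regions correlated with mPOA at r = 0.859 (permutation p = 1e-05, the smallest the permutations can give, adjusted p = 2e-05 over 2 genes). Spearman's rho was 0.782 (permutation p = 3e-05, adjusted p = 6e-05), and r was 0.772 without the 2 farthest replicates. For Avp, the other gene tested, r was 0.470 (permutation p = 0.00554, adjusted p = 0.00554), rho was 0.484 (permutation p = 0.00566, adjusted p = 0.00566), and r without the 2 farthest was 0.417. The labels give no batch, so no values within batches could be computed. The median share of the mPOA level of Oxt in the other regions was 0.166% in LConly and 0.409% in BLA. The medians do not show NACShell of FT, where Oxt was at 213 ± 75.1 CPM against 1547 ± 639 CPM in mPOA. The changes of Oxt and Avp over all regions that are given below mostly follow mPOA. The naming rule also counted their sign in the other regions, where their medians were low.

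**Figure D2:**
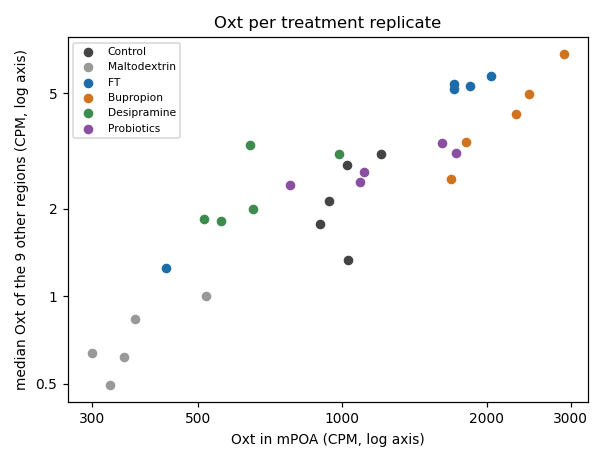
CPM of Oxt in mPOA (horizontal log axis) and the median CPM of Oxt over the 9 other regions (vertical log axis), 1 point per treatment replicate, with colours for the 6 treatments. Mean Oxt in mPOA lies between 373 CPM in Maltodextrin and 2230 CPM in Bupropion.

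FT was compared with Control to ask how gene expression differed with this drug in the 10 regions. Because the labels give no batch, a batch that followed the treatment cannot be told apart from a treatment effect in any of the 5 comparisons. Maltodextrin and Control, both of them control groups, differed for 7610 genes over all regions. Genes of antigen presentation were lower in FT. RT1-Ba, a chain of the MHC class II molecule, fell by 3.17 on the log2 scale over all regions together (SE 0.086, edgeR adjusted p = 4.49e-22, n = 5 treatment replicates per group), and was lower in 10 of 10 regions. Cd74 fell by 2.81 (SE 0.079, adjusted p = 6.89e-22), from 132 ± 4.4 to 19.5 ± 0.418 CPM. In CGC, mPOA, NACShell, PLC and Raphe alone, without the high levels in BLA and venDG of Control, RT1-Ba was at -0.83 and Cd74 at -0.71. Pomc, the precursor of several opioid and pituitary peptides, rose by 4.16 (SE 0.17, adjusted p = 4.35e-18), from 1.77 ± 0.38 to 39.8 ± 11.6 CPM, and its mean in mPOA of FT was 375 ± 112 CPM against 3.34 ± 1.07 CPM in Control. Avp, which encodes vasopressin, rose by 2.19 (SE 0.22, adjusted p = 1.03e-09), a change that mostly follows mPOA. Among the other genes that led in size, Plagl1, Pcsk1n and Sec14l3 rose by 2.02, 2.06 and 1.82, and RT1-Da, RT1-Db1, Cd68 and Il2rg had log2 changes of -3.04, -2.47, -1.55 and -1.53, with RT1-Da at -0.83 and RT1-Db1 at -0.61 in the 5 regions alone. Bc1, a small noncoding RNA of neurons, rose by 2.44 (SE 0.91, adjusted p = 0.0211). That call was lost without Control replicate 3, 4 or 5 (adjusted p from 0.0509 to 0.0526) or FT replicate 3 (log2 change 1.41, adjusted p = 0.173) and with the 5 regions alone (2.40, adjusted p = 0.057), and its size was 3.66 without Control replicate 1.

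Of 15 tested antigen presentation genes, 14 fell and 1 was not called in FT (camera adjusted p = 5.28e-06). Of 19 microglia genes, 16 fell and 3 were not called (adjusted p = 5.28e-06), with the fractalkine receptor Cx3cr1 at -0.96. Of 20 interferon response genes, 13 fell, 1 rose and 6 were not called (adjusted p = 0.000121), among them the antiviral genes Mx1 (-1.46) and Ifitm3 (-1.09). Vessel genes also moved down: of 20 members of the endothelium and mural cell list, 16 fell, 1 rose and 3 were not called (adjusted p = 6.37e-05), with Tagln, a protein of smooth muscle, at -1.21 and Rgs5, a pericyte marker, at -1.04. Sterol synthesis genes were lower, with 15 of 21 fallen, 2 risen and 4 not called (adjusted p = 0.0049); Fdft1, which commits isoprenoids to sterols, and Fdps, which makes its substrate, were at -0.70 and -0.59. Of 21 lysosome genes, 13 fell, 1 rose and 7 were not called (adjusted p = 0.00319; adjusted p = 0.2 with an estimated correlation), with the protease Ctsb at -0.75. Of 22 nuclear oxidative phosphorylation genes, 18 fell and 4 were not called (adjusted p = 0.00127; adjusted p = 0.197 with an estimated correlation), with Sdhb and Sdhd, subunits of complex II, at -0.95 and -0.71.

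Choroid plexus and ependyma genes rose in FT, 13 of 18 rising, 1 falling and 4 not called (adjusted p = 0.00136). Kl and Slc4a5 were at 0.89 and 0.84, and Rarres2 at -0.79. Ttr stood apart in BLA and dorDG of FT, as given above. Core clock genes rose, 10 of 16 rising, 1 falling and 5 not called (adjusted p = 0.0129), with the clock output gene Dbp at 0.45, Clock at 0.30 and Ciart at -0.37. Of 15 excitatory neuron genes, 7 rose, 2 fell and 6 were not called (adjusted p = 0.0421; adjusted p = 0.0649 with an estimated correlation). Neurod2 was at 1.00 and Neurod6 at -0.50. Of 19 preoptic and hypothalamic genes, 8 rose, 4 fell and 7 were not called (adjusted p = 0.0421; adjusted p = 0.0649 with an estimated correlation), with the peptide gene Cartpt at 1.29. Of 12 oligodendrocyte precursor genes, 8 rose and 4 were not called (adjusted p = 0.0442; adjusted p = 0.261 with an estimated correlation), with C1ql1 at 0.79. Adjusted over the list alone, these counts were the same for 11 of the 12 lists, and 14 choroid plexus genes rose instead of 13. The preoptic call was lost without FT replicate 1 (adjusted p = 0.106) or Control replicate 1 (0.0519), and the oligodendrocyte precursor call without Control replicate 1 or 3 or FT replicate 2, 3, 4 or 5 (0.0519 to 0.0749). Without ILC and LConly the calls for core clock (0.116), oligodendrocyte precursor (0.116), excitatory neuron (0.515), preoptic (0.0695) and oxidative phosphorylation genes (0.149) were lost. With only CGC, mPOA, NACShell, PLC and Raphe the oxidative phosphorylation call held, the other 4 were lost again (0.105 to 0.694) and so was the choroid plexus call (0.814), while Slc4a5 was at -0.027 (0.911).

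By region, the most genes differed between FT and Control in the libraries labelled ILC (9924), in those labelled LConly (9257) and in Raphe (7475), and the fewest in dorDG (3543). For ILC and LConly, FT libraries with the other label's markers were set against Control. Their counts and the changes given next for them cannot be read as effects of FT. In the libraries labelled ILC, Slc6a2, the noradrenaline transporter, was higher by 8.55 (SE 0.15, adjusted p = 2.45e-38) together with En2 (7.70) and Nefh (5.27), and Nov, Crym and Vip were at -6.25, -5.49 and -5.48. In those labelled LConly, Spp1 and Slc6a5, a glycine transporter, were at -9.13 and -5.60, Nts at -5.42, and Ddn, Arpp21 and Gas7 at 6.87, 4.54 and 4.50. Dbh, Th and Slc6a2 were at -8.07, -5.21 and -8.70 there (Slc6a2 at -10.01 without FT replicate 5), and these libraries carried the markers of the other label. In Raphe, Hcn2, a channel that paces firing, rose by 1.86 (SE 0.083, adjusted p = 1.2e-18), Igf2 by 1.71 and Olfm1 by 0.95, while Ube2n and Uqcc1 were at -1.46 and -1.41. Tph2 in Raphe fell by 0.42 (SE 0.061, adjusted p = 3.29e-07), and was at -0.047 against Control and Maltodextrin pooled (adjusted p = 0.454). Slc6a4, the serotonin transporter, was higher in Raphe by 0.12 (SE 0.048, adjusted p = 0.0296), a call lost without Control replicate 4 or FT replicate 2 or 5 (0.0787 to 0.0899), with no filter (0.147) or with only the groups compared (0.0776). Bdnf, a neurotrophin, rose by 0.41 in venDG (SE 0.059, adjusted p = 5.16e-07) and by 0.2 in dorDG (SE 0.075, adjusted p = 0.0415). The dorDG call was lost without any 1 of the Control replicates 1 to 5 or FT replicates 1, 2, 4 or 5 (0.057 to 0.164), and with DESeq2 (0.0651), RLE size factors (0.0681), no filter (0.0988) or the replicate block (0.0513). Fos, an immediate early gene, was at -0.32 over all regions (adjusted p = 3.98e-06), and Fkbp5, a target of the glucocorticoid receptor, at -0.027 (adjusted p = 0.497). Fkbp5 was at -0.069 (0.041) against the pooled groups and at 0.12 (0.00487) with only CGC, mPOA, NACShell, PLC and Raphe.

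Over all regions together, 9563 of 15427 genes differed between FT and Control in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3933 higher and 5630 lower, of which 140 and 730 by more than 2-fold. The difference between FT and Control varied between regions for 12667 of 13643 genes, with the libraries labelled ILC and LConly included, and 250 genes were called in the same direction in 10 of 10 regions. Without ILC and LConly, 3678 genes were higher and 5211 lower. In the 5 regions CGC, mPOA, NACShell, PLC and Raphe alone, 3959 genes were higher and 4261 lower, and Cxcl13 moved from -3.55 to -0.15 (adjusted p = 0.264).

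Bupropion was compared with Control for the same question. Cxcl13 fell by 3.38 over all regions (SE 0.090, adjusted p = 3.8e-22, n = 5 per group), from 14.1 ± 0.86 to 1.2 ± 0.0844 CPM, and RT1-Ba, Cd74, RT1-Da, Plac8 and RT1-Db1 were at -3.01, -2.84, -2.87, -2.36 and -2.08. Pink1, a kinase that marks damaged mitochondria, rose by 1.28 (SE 0.072, adjusted p = 1.36e-14), from 66.6 ± 2.83 to 158 ± 14.9 CPM and in 10 of 10 regions. Avp rose by 1.33 (SE 0.22, adjusted p = 7.28e-06) and Oxt by 1.18 (SE 0.28, adjusted p = 0.0006), changes that mostly follow mPOA. Syndig1l, Rcan3 and Rps2 rose by 1.17, 1.12 and 1.12. The class II genes and Cxcl13 stood at 95.5 ± 4.1 (RT1-Ba in BLA) and 109 ± 7.68 CPM (Cxcl13 in venDG) in Control, and with only CGC, mPOA, NACShell, PLC and Raphe the changes of RT1-Db1 and Plac8 were -0.12 (adjusted p = 0.264) and -0.17 (0.0946). Those of Cxcl13, RT1-Ba, Cd74 and RT1-Da were -0.40, -0.47, -0.58 and -0.50 there.

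Neuropeptide genes rose with Bupropion, 16 of 22 rising, 4 falling and 2 not called (camera adjusted p = 2.88e-05), among them Tac3 (0.58), Pnoc (0.53) and Pdyn (0.30), the precursors of neurokinin B, nociceptin and dynorphins. Of 19 preoptic and hypothalamic genes, 9 rose and 10 were not called (adjusted p = 0.0049), with Six3 at 0.82 and Gal, which encodes galanin, at 0.55. Genes of striatal projection neurons rose, 14 of 18 rising and 4 falling (adjusted p = 1.23e-05; adjusted p = 0.111 with an estimated correlation), with the retinoid receptor Rxrg at 0.47 and the adenosine receptor Adora2a at 0.43. By region, the striatal list was higher in CGC, LConly and venDG, and it was called in 2 regions with an estimated correlation. It was not called in NACShell, the region marked by Drd1 above. Of 15 antigen presentation genes, 12 fell and 3 were not called (adjusted p = 0.000164). Of 15 excitatory neuron genes, 7 rose, 3 fell and 5 were not called (adjusted p = 0.00385), with Tle4 at -0.19. Of 16 GABAergic neuron genes, 9 rose, 2 fell and 5 were not called (adjusted p = 0.0421; adjusted p = 0.0649 with an estimated correlation), with Dlx5 at 0.64, while Gad1, an enzyme that makes GABA, and Adarb2 were at -0.26 and -0.92. Of 12 oligodendrocyte precursor genes, 7 rose, 1 fell and 4 were not called (adjusted p = 0.0442; adjusted p = 0.261 with an estimated correlation), with Gpr17 at 0.51. Adjusted over the list alone, the counts were the same except that 3 GABAergic genes fell. The GABAergic call was lost without Bupropion replicate 1 (0.0531), and the oligodendrocyte precursor call without Control replicate 1 or 3 or Bupropion replicate 1 or 4 (0.0519 to 0.0563). Without ILC and LConly the excitatory, oligodendrocyte precursor and GABAergic calls were lost (0.12, 0.12 and 0.276). With only CGC, mPOA, NACShell, PLC and Raphe the antigen presentation and striatal calls were lost as well (0.147 and 0.346), and Adora2a was at 0.037 (adjusted p = 0.562).

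The most genes differed between Bupropion and Control in ILC (8783), LConly (7370) and BLA (6437). The fewest did in dorDG (1941, but 4212 with only the groups compared and 3498 with surrogate variables). ILC held the most calls in each comparison against Control, whose ILC libraries stood apart, so its rank is not particular to Bupropion. In ILC, Slc17a7 was higher by 3.85 (SE 0.089, adjusted p = 6.68e-29), from 23.4 ± 2.48 CPM in Control, with Bnip3 and Ppp3r1, the regulatory subunit of calcineurin, at 2.93 and 2.64, and Ociad2 and Vps29 at -2.36 and -2.18. In LConly, Ppp1r1b and Rgs9, signalling genes of striatal neurons, were higher by 2.90 and 2.66 and Ddn by 2.68, and Prepl, Slc3a1 and Cd200 were at -1.51, -1.39 and -0.88. In BLA, Myl12b, Nptxr and Syn1 were at 1.79, 1.65 and 1.52, and RT1-Ba, RT1-Da and RT1-Db1 at -6.56, -6.33 and -4.37. Th, the rate-limiting enzyme of catecholamine synthesis, rose in LConly by 1.17 (SE 0.079, adjusted p = 6.85e-14), from 67.5 ± 7.78 to 152 ± 7.89 CPM, and Dbh by 0.59 (SE 0.073, adjusted p = 3.16e-08). Slc6a2 was at -0.21 (SE 0.089, adjusted p = 0.046), a call lost without any 1 of the Control replicates 1 to 5 or Bupropion replicates 1 to 4 (0.0512 to 0.127), with RLE size factors (0.0778) or with no filter (0.11). Tph2 in Raphe fell by 0.87 (SE 0.061, adjusted p = 1.03e-12), and Slc6a4 was at -0.097 (adjusted p = 0.0983), at -0.12 with surrogate variables (0.0471) and at 0.14 against Control and Maltodextrin pooled (0.00538). Maltodextrin against the same Control moved Tph2, Th and Dbh in the same directions, so these changes are not shown to be particular to Bupropion. Bdnf was at 0.24 in dorDG (adjusted p = 0.0234) and 0.19 in venDG (adjusted p = 0.0105). The former was not called without Control replicate 1, 2, 4 or 5 or Bupropion replicate 1 (0.0676 to 0.0972), and the latter without Control replicate 3 or Bupropion replicate 1 (0.0576 and 0.0569) or against Control and Maltodextrin pooled (0.256). Fkbp5 was at -0.0071 (adjusted p = 0.865) and Fos at -0.14 (adjusted p = 0.0137). The call of Fos was lost with limma on mean log2 CPM (-0.050, adjusted p = 0.43), without ILC and LConly (-0.11, 0.0892) and with only CGC, mPOA, NACShell, PLC and Raphe (-0.15, 0.057).

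In total 9080 of 15427 genes differed between Bupropion and Control, 3459 higher and 5621 lower (38 and 1046 by more than 2-fold), and 141 were called in the same direction in 10 of 10 regions. The difference from Control varied between regions for 12723 of 13983 genes, with the Control libraries that stood apart in ILC, BLA and venDG included. Restricted to CGC, mPOA, NACShell, PLC and Raphe, 3423 genes were higher and 3673 lower.

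Desipramine was also compared with Control. Cxcl13 fell by 3.60 (SE 0.095, adjusted p = 1.87e-22, n = 5 per group), RT1-Ba by 3.47 in 10 of 10 regions and Cd74 by 3.36, and RT1-Da and RT1-Db1 were at -3.10 and -2.76. In CGC, mPOA, NACShell, PLC and Raphe alone, without BLA and venDG of Control, these genes were at -0.27 (adjusted p = 0.0474), -1.20, -1.16, -0.77 and -0.87 in the same order. Morn5 fell by 3.24 (SE 0.32, adjusted p = 5.95e-10), from 288 ± 71.7 to 36.2 ± 7 CPM. Fut7, a fucosyltransferase, rose by 1.43 (SE 0.19, adjusted p = 1.7e-07). Aard, Gstcd, Mip and Rbm24 rose by 3.05, 2.44, 1.47 and 1.39, with their highest values in replicate 3, whose BLA library held 198260 counts. Without Desipramine replicate 3, Gstcd was at 0.35 (adjusted p = 0.0557), Mip at 0.49 (0.167) and Aard at 0.66 (0.0113). Mip was also not called without the 4 libraries below 1000000 counts (0.148), and Gstcd not with only the groups compared (0.0697). The level of Rbm24 in that replicate was 457 CPM against a group mean of 117 ± 191 CPM. Its call held without that replicate and was lost with only CGC, mPOA, NACShell, PLC and Raphe (0.90, adjusted p = 0.122). With the main axis of variation within groups as a covariate, Rbm24 (0.85, adjusted p = 0.222), Aard (1.12, 0.353) and Gstcd (0.82, 0.464) were not called. Over all genes tested the median log2 change was -0.12, and a call does not subtract it.

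Of 15 antigen presentation genes, 14 fell and 1 was not called with Desipramine (camera adjusted p = 5.08e-06). Interferon response genes fell, 14 of 20 falling, 2 rising and 4 not called (adjusted p = 0.0049), with Irf7, a regulator of interferon genes, at -1.28. Of 19 microglia genes, 16 fell, 2 rose and 1 was not called (adjusted p = 0.00215; adjusted p = 0.197 with an estimated correlation), among them the complement gene C1qc (-1.59) and Ctss (-0.66). Of 21 lysosome genes, 13 fell, 1 rose and 7 were not called (adjusted p = 0.0356; adjusted p = 0.363 with an estimated correlation), with Psap and Ctsb at -0.65 and -0.62. Core clock genes rose, 11 of 16 rising, 2 falling and 3 not called (adjusted p = 0.00032), with Rorb at 0.63, the repressor Nr1d2 at 0.40 and Clock at 0.36. Of 15 excitatory neuron genes, 6 rose, 4 fell and 5 were not called (adjusted p = 0.00319), with the kinase Camk2a at -0.78 and Bcl11b at 0.48, which was at 0.073 (adjusted p = 0.159) with the main axis of variation within groups as a covariate. Of 16 GABAergic neuron genes, 6 rose, 7 fell and 3 were not called, and camera placed the list above other genes (adjusted p = 0.0442; adjusted p = 0.0661 with an estimated correlation); its median was 0.03 and its mean -0.02, so these differ in sign. Reln, Slc32a1 and Gad1 were at 0.51, 0.48 and 0.43. Adjusted over the list alone, 3 interferon genes rose and 3 clock genes fell, and the other counts were the same. The GABAergic call was lost with the replicate block. Without ILC and LConly the interferon, excitatory and GABAergic calls were lost (0.0605, 0.132 and 0.303). With only CGC, mPOA, NACShell, PLC and Raphe the clock call was lost too (0.058), and Mx1 and Fcgr3a moved from -1.17 and -1.14 to -0.17 (0.187) and -0.073 (0.46).

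The most genes differed between Desipramine and Control in ILC (8770), where the Control libraries stood apart, mPOA (8000) and Raphe (7347), and the fewest in dorDG (3904). In mPOA, the contractile genes Tagln, Myl9 and Tpm2 were at -2.25, -1.98 and -1.77 (Tagln adjusted p = 4.71e-22), and Dact3, Rpl30 and Cmas at 1.24, 1.02 and 0.96. In Raphe, Ddn, Arpp21 and Rpl30 were at 2.28, 1.45 and 1.32, and Atp6v0d1 and Syt11 at -1.18 and -1.13. In ILC, Ppp3r1, Slc17a7 and Tnpo2 were at 3.36, 3.33 and 2.45, and H3f3b and Vps29 at -3.06 and -2.70, with Slc17a7 at 23.4 ± 2.48 CPM in ILC of Control. The noradrenergic genes were lower in LConly: Slc6a2, the transporter this drug blocks, fell by 1.66 (SE 0.095, adjusted p = 2.57e-16), from 68.6 ± 4.36 to 26 ± 1.77 CPM, Dbh by 1.42 (SE 0.076, adjusted p = 3.23e-16) and Th by 1.19 (SE 0.083, adjusted p = 1.9e-13). Gabra6, a receptor subunit of cerebellar granule cells, was at 99.8 ± 11.1 CPM in the same LConly libraries and at 8.23 ± 1.06 CPM in Control. A difference in the tissue punched was not tested and cannot be told apart from a change in the noradrenergic genes. Tph2 in Raphe fell by 0.26 (adjusted p = 0.000376), and was at 0.11 against Control and Maltodextrin pooled (adjusted p = 0.0666). Slc6a4 in Raphe was at 0.094 (adjusted p = 0.0895), and was called without Control replicate 1, 2 or 3 or Desipramine replicate 4 (0.0248 to 0.0472), with DESeq2 (0.0393) and against Control and Maltodextrin pooled (0.33, adjusted p = 2.64e-08). Bdnf was at -0.0011 in dorDG and -0.052 in venDG (adjusted p = 0.994 and 0.466), and in venDG at -0.17 against the pooled groups (0.00688). Fos fell by 0.53 (SE 0.051, adjusted p = 2.54e-10), and Fkbp5 rose by 0.11 (adjusted p = 0.00441).

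Over all regions 10883 of 15427 genes differed between Desipramine and Control, 4014 higher and 6869 lower (52 and 1627 by more than 2-fold), and 526 were called in the same direction in 10 of 10 regions. The difference from Control varied between regions for 12044 of 13682 genes, again with the Control libraries that stood apart included. When only CGC, mPOA, NACShell, PLC and Raphe were used, 4325 genes were higher and 4968 lower.

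Maltodextrin, the carrier of the probiotic, was compared with Control, the group on water. Cd74 fell by 2.72 over all regions (SE 0.078, adjusted p = 3.07e-21, n = 5 per group), from 132 ± 4.4 to 21.1 ± 0.606 CPM, and RT1-Db1 by 2.24; in the 5 regions without BLA and venDG, Cd74 was at -0.31 (adjusted p = 0.00287). Oxt fell by 1.55 (SE 0.29, adjusted p = 5.55e-05), from 104 ± 12.4 to 38 ± 8.62 CPM, a change that mostly follows mPOA. Slc6a5, the glycine transporter of inhibitory neurons, rose by 1.14 (SE 0.037, adjusted p = 4.21e-20), and Ttr by 0.86 (SE 0.087, adjusted p = 5.61e-09), with 6222 ± 404 CPM of Ttr in Maltodextrin LConly. Fut7, Sec14l3 and Crhbp rose by 1.07, 0.99 and 0.71, and Il2rg, Morn5 and Hes5 were at -1.32, -1.20 and -1.12. Fibcd1 rose by 0.74 (adjusted p = 0.016), a call lost without Maltodextrin replicate 3 (0.0592) and with limma on mean log2 CPM (0.0777). With only CGC, mPOA, NACShell, PLC and Raphe, RT1-Db1, Ttr, Il2rg and Fibcd1 were at -0.10 (0.34), 0.093 (0.509), -0.30 (0.104) and 0.57 (0.192).

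Of 15 antigen presentation genes, 14 fell and 1 rose with Maltodextrin (camera adjusted p = 8.36e-08), with RT1-Ba and RT1-Da at -2.73 and -2.48. Of 19 microglia genes, 17 fell and 2 were not called (adjusted p = 1.69e-06), among them Cd68 (-1.46), Fcgr3a (-1.12) and Csf1r (-0.34), the receptor microglia need to survive. Of 21 lysosome genes, 10 fell, 1 rose and 10 were not called (adjusted p = 0.00991; adjusted p = 0.261 with an estimated correlation), with Ctsz and Ctsb both at -0.52. Choroid plexus and ependyma genes rose, 12 of 18 rising, 1 falling and 5 not called (adjusted p = 0.000305), with Cldn2 at 0.72 and Kcnj13 at 0.45. Cytosolic ribosomal protein genes rose, 9 of 23 rising and 14 not called (adjusted p = 0.00048; adjusted p = 0.261 with an estimated correlation), with Rps7 at 0.32 and Rpl27 at 0.31. Immediate early genes moved both ways, 10 of 21 rising, 5 falling and 6 not called (adjusted p = 0.00914; adjusted p = 0.0649 with an estimated correlation), with Egr4 and Homer1 at 0.49 and 0.42 and Nptx2 at -0.69. Of 20 neurotrophic and CREB target genes, 9 rose, 1 fell and 10 were not called (adjusted p = 0.0213; adjusted p = 0.243 with an estimated correlation), with Vegfa at 0.61 and Ntf3 at -0.23. Of 16 clock genes, 8 rose, 2 fell and 6 were not called (adjusted p = 0.014), with Clock at 0.30 and Ciart at -0.34. Adjusted over the list alone, 1 microglia gene rose besides the 17 that fell, 8 ribosomal genes rose, and the other counts were the same.

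Without ILC and LConly the Maltodextrin calls for immediate early (0.796), clock (0.189) and choroid plexus genes (0.509) were lost, and Ntf3 was at 0.018 (0.796) and Cldn2 at 0.20 (0.1). In CGC, mPOA, NACShell, PLC and Raphe alone, antigen presentation (0.128) and neurotrophic genes (0.157) were lost as well, and the immediate early list pointed down (0.237). In those regions RT1-Ba was at -0.027 (0.827), RT1-Da at 0.18 (0.0899), Fcgr3a at 0.077 (0.453) and Cd68 at -0.21 (0.166).

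Between Maltodextrin and Control, 8367 genes differed in ILC, where the Control libraries stood apart, 5980 in PLC, 5735 in LConly and 128 in dorDG. The dorDG count was 40 to 74 when replicates were left out, 61 with no filter, 610 with surrogate variables and 1021 with only the groups compared. In ILC, Ppp3r1, Bnip3 and Tnpo2 were at 3.53, 2.66 and 2.36 and H3f3b and Vps29 at -2.53 and -2.22. In PLC, Napg, Tmx4 and Srpk2 were at 0.61, 0.57 and 0.55, and Spata2L, Syn1, a protein of synaptic vesicles, and Ppp1r9b at -2.28, -1.88 and -1.74. In LConly, the choroid plexus genes Ttr, Cldn2 and Kcnj13 were higher by 7.16, 6.14 and 3.69, and Tac1, Gstm1 and Calb1 were at -1.61, -1.50 and -1.16. Cldn2 there was at 6.93 without Control replicate 5. Tph2 in Raphe fell by 0.75 (SE 0.061, adjusted p = 5.51e-11), from 751 ± 25.4 to 464 ± 12.6 CPM, and Slc6a4 by 0.48 (adjusted p = 4.5e-09). Th, Dbh and Slc6a2 were higher in LConly by 0.86, 0.59 and 0.36 (adjusted p = 2.59e-10, 9.88e-08 and 0.00135). Bdnf was at 0.23 in venDG (adjusted p = 0.00493) and -0.016 in dorDG (0.985). Fkbp5 was at 0.084 (adjusted p = 0.0342), a call lost without Control replicate 3 or 4 or Maltodextrin replicate 1 (0.0631 to 0.11), and Fos at 0.039 (0.534). Fos was called without ILC and LConly (0.15, adjusted p = 0.0244) and with only CGC, mPOA, NACShell, PLC and Raphe (0.16, 0.0392).

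In this comparison 7610 of 15427 genes differed, 2708 higher and 4902 lower (19 and 807 by more than 2-fold), and none was called in the same direction in 10 of 10 regions, with edgeR. Of the genes called in single regions, 6352 were called in both directions. The difference between these groups varied between regions for 12469 of 13750 genes, with the Control libraries that stood apart included. With only CGC, mPOA, NACShell, PLC and Raphe, 3679 genes were higher and 3808 lower, a share of 49.1% higher against 35.6% with 10 regions.

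Probiotics were compared with Maltodextrin, their carrier. Il2rg, the common receptor chain of several interleukins, rose by 2.37 over all regions (SE 0.16, adjusted p = 4.17e-13, n = 5 per group), from 1.09 ± 0.208 to 5.53 ± 1.9 CPM and in 10 of 10 regions. Tubb4a, a tubulin of neurons and oligodendrocytes, rose by 1.65 (SE 0.10, adjusted p = 8.69e-14), from 606 ± 14.3 to 1868 ± 71 CPM. Tox2, Dapk3 and Clip3 rose by 1.92, 1.84 and 1.81. Oxt rose by 1.65 (SE 0.29, adjusted p = 1.59e-05), a change that mostly follows mPOA, and against Control was at 0.095 (adjusted p = 0.788). Rasd1, a Ras-like protein induced by dexamethasone, fell by 1.22 (SE 0.052, adjusted p = 2.49e-17), from 12.9 ± 0.301 to 6.06 ± 0.485 CPM, and Mir221, Mir3064, Nmbr and Lrrc14b were at -1.29, -1.20, -1.12 and -1.10. Sec14l3 fell by 1.14, and against Control was at -0.15 (adjusted p = 0.623).

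Of 22 nuclear oxidative phosphorylation genes, 13 fell, 1 rose and 8 were not called with Probiotics (camera adjusted p = 1.69e-06), and the list was lower in 8 of 10 regions, all but dorDG and venDG, but in only 1 of these with an estimated correlation. Cox7c and Cox6c, subunits of cytochrome c oxidase, were at -0.92 and -0.63, and Sdhd at -0.82. Of 23 cytosolic ribosomal protein genes, 12 fell, 3 rose and 8 were not called (adjusted p = 0.00129; adjusted p = 0.298 with an estimated correlation), with Rpl3, Rpl27 and Rps3 at -0.52, -0.49 and -0.43. Adjusted over the list alone, the counts of both lists were the same. The median log2 change of all genes was 0.072.

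Between Probiotics and Maltodextrin, 8299 genes differed in dorDG, 6407 in venDG, 6237 in ILC and 2760 in BLA. The BLA count was 4326 with only the groups compared and 6439 against Control. In dorDG, Slc17a7, Ppp3r1 and Naa20 were at -3.87, -3.71 and -3.34 (Ppp3r1 adjusted p = 3.5e-26), and Stam2, Timm17a and Commd4 at 3.43, 2.72 and 2.46. Mbp stood at 597 ± 39.6 CPM and Prox1 at 29.6 ± 7.38 CPM in these libraries, against 5799 ± 682 and 88.9 ± 3.49 CPM in Maltodextrin dorDG. Across 11757 genes, which are not independent replicates, the changes with Probiotics in dorDG correlated with those with Maltodextrin in ILC at r = -0.693, and of 6341 genes called in both, 5795 moved in opposite directions. In venDG, Slc12a2, Sec61g and Enpp2, an enzyme abundant in choroid plexus, were at -2.02, -2.01 and -1.37, and Myl12b, Myt1l and Cfdp1 at 1.58, 1.05 and 0.96. In ILC, Wbp2, the muscarinic receptor Chrm1 and Ppp1r9b were at 2.58, 2.58 and 1.29, and Rap2c, Eif4a2 and Chmp3 at -0.91, -0.75 and -0.72; Eif4a2 was at 0.20 against Control (adjusted p = 0.000795). Bdnf was higher in dorDG by 1.18 (SE 0.074, adjusted p = 1.39e-15) and in venDG by 0.36 (SE 0.058, adjusted p = 2.37e-06). Because the dorDG libraries of Probiotics stood apart in Slc17a7, Mbp and Prox1, the dorDG value cannot be read as an effect of Probiotics. Dbh was at 0.32 in LConly (adjusted p = 0.000648), Slc6a2 at -0.47 (adjusted p = 5.24e-05; -0.12 and 0.271 against Control) and Th at 0.033 (adjusted p = 0.766; 0.89 and 2.51e-11 against Control). Tph2 in Raphe was at -0.16 (adjusted p = 0.0326), not called without Maltodextrin replicate 3 or 5 or Probiotics replicate 1, 3 or 4 (0.0634 to 0.174), with surrogate variables (-0.090, 0.171) or with only the groups compared (-0.14, 0.0519). Slc6a4 there was at 0.017 (0.82), and at -0.46 against Control (adjusted p = 2.74e-09). Fos and Fkbp5 were at 0.092 and 0.051 (adjusted p = 0.113 and 0.184). Without Maltodextrin replicate 4 or Probiotics replicate 2, Fos was called (0.0352 and 0.0474), as it was with limma on mean log2 CPM (0.0186), with the axis covariate (0.0231) and against Control (0.0237). Fkbp5 was at 0.13 against Control (0.000822).

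Over all regions 8797 of 15427 genes differed between Probiotics and Maltodextrin, 5375 higher and 3422 lower (630 and 31 by more than 2-fold), and 324 were called in the same direction in 10 of 10 regions. The difference from Maltodextrin varied between regions for 10878 of 13062 genes, with the dorDG libraries of Probiotics that stood apart included. From CGC, mPOA, NACShell, PLC and Raphe alone, 3608 genes were higher and 3625 lower, a share of 49.9% higher against 61.1% with 10 regions.

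**Figure D3:**
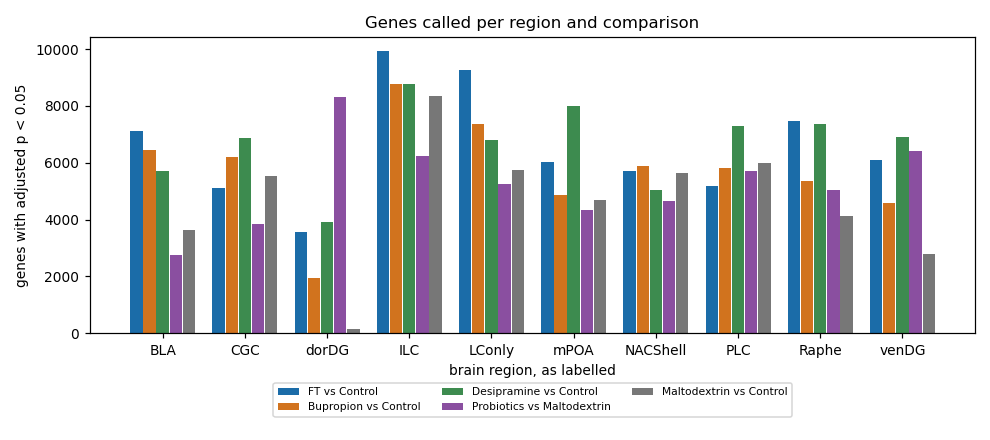
Number of genes with an adjusted p under 0.05 (vertical axis) in each of the 10 regions (horizontal axis) for the 5 comparisons, from edgeR on the 30 libraries of each region. FT, Bupropion, Desipramine and Maltodextrin have their highest bars in ILC (9924, 8783, 8770 and 8367) and Probiotics in dorDG (8299), while Maltodextrin has 128 in dorDG.

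The other gene lists fixed before the data were examined were called in no comparison over all regions. Their lowest adjusted p over the 5 comparisons was 0.542 for monoamine synthesis, transport and breakdown, 0.738 for monoamine receptors, 0.339 for glucocorticoid response, 0.176 for heat shock, 0.0839 for unfolded protein response and 0.436 for inflammatory cytokines. For dentate neurogenesis it was 0.0657, for dentate granule cells 0.279, for oligodendrocyte and myelin 0.156, for astrocyte 0.125, for meninges and fibroblasts 0.52, for red blood cells 0.542, for locus coeruleus noradrenergic cells 0.502 and for raphe serotonergic cells 0.436. Members of the uncalled lists still moved in single regions: the locus coeruleus list was lower in LConly with Desipramine and in the FT libraries labelled LConly, and higher in those labelled ILC, also with an estimated correlation. Of 160 list tests 36 were called, and 20 with an estimated correlation; at the level of single regions 345 of 1600 were called, and 137 with an estimated correlation.

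The drugs were also tested against each other, since a gene called for 1 drug and not for another is not thereby shown to differ. FT and Bupropion differed for 8935 genes (4603 higher and 4332 lower in FT), FT and Desipramine for 9494 (5306 higher and 4188 lower in FT), and Bupropion and Desipramine for 10839 (5889 higher and 4950 lower in Bupropion). The change from Control with a drug was set against the change from Maltodextrin with Probiotics in the same way. It differed for 9036 genes with FT (3164 more positive with FT, 5872 less), 7209 with Bupropion (2119 and 5090) and 11088 with Desipramine (3830 and 7258).

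Genes called in the same direction in several comparisons with the smallest adjusted p included Fcnb, a ficolin of myeloid cells, Cxcl13, RT1-Db1 and RT1-Da. Fcnb was at -4.61, -4.40, -4.79 and -4.65 in FT, Bupropion, Desipramine and Maltodextrin against Control and at 1.00 in Probiotics against Maltodextrin, and it was tested in 2 regions. Cxcl13 was at -3.50 in Maltodextrin and at 0.053 in Probiotics (adjusted p = 0.734), where it was called with limma on mean log2 CPM (0.38, adjusted p = 0.00171) and with the axis covariate (0.26, 0.0426). The comparisons against Control share its libraries, and class II genes and Cxcl13 stood apart in Control BLA or venDG. In CGC, mPOA, NACShell, PLC and Raphe alone, Cxcl13 was at -0.15 (0.264) in FT and 0.020 (0.894) in Maltodextrin, and Fcnb at -0.78 in Bupropion and -0.91 in Maltodextrin. There RT1-Db1 was at -0.12 (0.264) in Bupropion and -0.10 (0.34) in Maltodextrin, and RT1-Da at 0.18 (0.0899) in Maltodextrin. Cryzl1 was at -1.11, -0.67, -0.91 and -0.61 in the same groups against Control. Without ILC and LConly it was at -0.028 (adjusted p = 0.517) in Bupropion and 0.10 (0.0182) in Maltodextrin. Syvn1, a ubiquitin ligase of the endoplasmic reticulum, was higher in FT, Bupropion and Probiotics by 0.45, 0.50 and 0.68, and Jup, a junction protein, by 0.59, 0.64 and 0.81. In Desipramine, Syvn1 at 0.041 and Jup at 0.079 were not called. There they were called higher with limma on mean log2 CPM (0.081 and 0.154) and lower with only CGC, mPOA, NACShell, PLC and Raphe (-0.11 and -0.125). Tspan5 was higher by 0.38, 0.48, 0.35 and 0.42 in FT, Bupropion, Desipramine and Probiotics. Srsf5, a splicing factor, fell by 0.63, 0.94 and 0.70 in FT, Bupropion and Probiotics, and was at 0.10 in Maltodextrin (adjusted p = 0.0305), a call lost without Control replicate 4 or 5 or Maltodextrin replicate 1, 2 or 3 (0.0505 to 0.107). In Maltodextrin Srsf5 was at -0.005 (0.925) without ILC and LConly and at 0.012 (0.816) with only CGC, mPOA, NACShell, PLC and Raphe.

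Comparisons against the same Control libraries share their chance values, so their overlap was set beside simulated unchanged groups and beside a fit with the controls split. Neither can tell a shared effect of the treatments from a Control group that stood apart as a whole. A split leaves such a shift in both parts, and the simulation drew none. All-region changes with FT and Bupropion correlated at r = 0.68 across 15427 genes (covariance 0.191), against r = 0.496 (covariance 0.0109) in simulated unchanged groups and r = 0.63 (covariance 0.182) with Control replicates split between them. Both called 5443 genes in the same direction and 980 in opposite directions, against 882 higher and 2051 lower for independent lists, 0 in the simulation and 4387.5 with split controls. FT and Desipramine called 6677 genes in the same direction and 799 in opposite directions (independent lists 1023 and 2507, split controls 5720.5; r = 0.684, simulated 0.473, split 0.652; covariance 0.312, simulated 0.0107). Bupropion and Desipramine called 4409 in the same direction and 2391 in opposite directions (independent lists 900 and 2503, split controls 3523; r = 0.715, simulated 0.503, split 0.686; covariance 0.371, simulated 0.0109). Desipramine and Maltodextrin called 6318 in the same direction and 288 in opposite directions (independent lists 705 and 2183, split controls 4928.5; r = 0.843, simulated 0.493, split 0.802; covariance 0.352, simulated 0.0109). FT and Maltodextrin called 4731 in the same direction and 895 in opposite directions (independent lists 690 and 1789, split controls 3567; r = 0.645, simulated 0.48, split 0.59; covariance 0.146, simulated 0.0107), and Bupropion and Maltodextrin 3064 and 2048 (independent lists 607 and 1786, split controls 2198.5; r = 0.676, simulated 0.506, split 0.625; covariance 0.174, simulated 0.0108).

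The drugs and Probiotics share no control libraries. Bupropion and Probiotics called 4216 genes in the same direction and 1548 in opposite directions (independent lists 1205 higher and 1247 lower), FT and Probiotics 3397 and 2411 (1370 and 1249), and Desipramine and Probiotics 2321 and 4136 (1399 and 1524). Across genes, r was -0.163, -0.0884 and -0.449 with covariances of -0.0397, -0.0189 and -0.178, while simulated unchanged groups gave r of -0.00184, -0.000104 and -0.00948. With only CGC, mPOA, NACShell, PLC and Raphe, r was positive for Bupropion and for FT and stayed negative for Desipramine. Probiotics and Maltodextrin, whose comparisons use the Maltodextrin libraries on opposite sides, called 948 in the same direction and 3896 opposite (independent lists 944 and 1087, split libraries 570; r = -0.565, simulated -0.514, split -0.478; covariance -0.111, simulated -0.0112). With the 3 drugs, 1082 genes were higher and 2639 lower in each. Of these, 623 and 717 moved the same way with Probiotics, and 256 and 280 in each of the 5 comparisons. No simulated or split-control value was computed for these counts, and the drugs share the Control libraries.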

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

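The tests of the 3 patterns weighed here, and the splits for the all-region counts, the FT region-level count and the FT test of differences between regions, were chosen only after the result was seen.

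The FT libraries labelled ILC held locus coeruleus markers, and those labelled LConly held cortical ones. The tables argue against a mixed sample, since the median level of Dbh, Slc6a2 and Th in the FT libraries labelled LConly was 0.350% of that of the other treatments. They also argue against FT itself switching these genes on in cortex: the highest mean of Dbh in CGC and PLC of FT was 0.747 CPM. Exchanged labels are a candidate explanation that stays open, since 10 of the 10 FT libraries correlated better with the other label's mean profile in the other treatments than with their own label's. An earlier form of this test, which asked whether the other label was the nearest of all 10 regions, gave 6 of 10 and was replaced after it was seen.

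Between Maltodextrin and Control, both of them control groups, 7610 genes differed. Unequal library size as the whole cause is argued against: with all libraries thinned to 4451412 counts, 7016 genes were called, against 9183 at full depth. The main axis of variation within groups, which held 62.5% of that variance, is argued against as the whole cause, with 7061 genes called when it was a covariate, although 37.7% of the squared fold change lay along it, a share that was the first form of the test and decided nothing. FT replicate 1, whose libraries held 3511756 to 4807308 counts, largely set this axis, with a score of -33.1 while the others lay between -3.02 and 11.2. A library batch that followed the treatment and an effect of the sugar cannot be told apart, because the labels give no batch; the coefficient of variation between treatment replicates of a group was 7.54%.

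Oxt outside mPOA followed Oxt in mPOA over the 30 treatment replicates, centred within treatments (r = 0.859). An effect of treatment on Oxt was tried as a cause and dropped: the share of the mPOA level in the other regions (0.166% to 0.409%) decided nothing, and centring takes out such an effect by construction. Reads carried over between libraries of a treatment replicate may explain it and stay open: Avp, another gene of mPOA, followed its own mPOA level too (r = 0.470, permutation p = 0.00554). An even carry-over leaves unexplained Oxt at 213 CPM in NACShell of FT. Neurons that contain oxytocin outside mPOA and differences between rats of a group were not tested and stay open.

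Single libraries or treatment replicates lay far from the other 4 of their group in 24 of 212 groups tested. Chance flags about 1 in 20 groups. Total counts stood apart at 13791907 in Maltodextrin LConly replicate 1, 3692669 in FT LConly replicate 1 and 198260 in Desipramine BLA replicate 3. Desipramine replicate 1 stood apart in CGC (841455), dorDG (825020), mPOA (8556614) and NACShell (571357). FT replicate 1 stood apart over all regions in Pomc (19.1 CPM), Avp (33.9 CPM), Sec14l3 (12.1 CPM) and Fos (10.6 CPM). Desipramine replicate 3 did so in Aard (1217 CPM), Gstcd (995 CPM), Mip (1047 CPM), Rbm24 (457 CPM) and Fkbp5 (37.0 CPM). In LConly, Dbh stood apart at 0.115 CPM in FT replicate 4 and at 162 CPM in Control replicate 5, and in dorDG Bdnf did so at 224 CPM in Bupropion replicate 1. Over all regions the others were Bc1 at 52.4 CPM in Control replicate 1, Ttr at 1131 CPM in Control replicate 2, Tubb4a at 630 CPM in Maltodextrin replicate 5, Mir221 at 0.836 CPM in Probiotics replicate 3 and Fos at 10.7 CPM in Probiotics replicate 2.

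Group differences that varied between regions, and drug groups that differed from each other or from Probiotics, were found by tests of the difference itself. Groups that stood apart in single regions enter the test between regions. Its counts therefore cannot be read as treatment effects particular to a region. Over 24 splits of the treatment replicates, the real one gave the most genes that differed between regions: FT had 12667 genes (highest other split 8815), Bupropion 12723 (8190), Desipramine 12044 (6566), Probiotics 10878 (5733) and Maltodextrin 12469 (7523). So few splits cannot show a share under 1 in 24, so chance is made unlikely but not excluded. Over 100 splits the real one gave the most genes for the differences of FT from Bupropion (8935, highest other 5827) and Desipramine (9494, 8579), and of Bupropion from Desipramine (10839, 7359). Chance is made unlikely there as well. For the effects set against that of Probiotics the real grouping also gave the most genes, with 9036 for FT (3257), 7209 for Bupropion (3412) and 11088 for Desipramine (2520). Those splits shuffled all groups of the contrast together, so they ask whether any group differs. They cannot decide whether the effects themselves differ.

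For the comparisons themselves, 1 of 100 splits, the real one, gave as many genes over all regions: 9563 for FT (highest other 5645), 9080 for Bupropion (4511), 10883 for Desipramine (6751), 8797 for Probiotics (3836) and 7610 for Maltodextrin (2553). Chance is thus made unlikely, but 100 splits cannot show a share under 1 in 100. Of 40 splits the real one also gave the most calls summed over single regions: 65461 for FT (30740), 57250 for Bupropion (19109), 66648 for Desipramine (27280), 52565 for Probiotics (13848) and 46602 for Maltodextrin (12746). Splits speak to chance but not to a batch that follows the treatment. For the number of called gene lists, the real grouping of FT gave the most of 100 splits, with 12 lists (highest other 11). That makes chance unlikely but does not exclude it, and several of these calls were lost without ILC and LConly. Chance was not made unlikely for Bupropion (7 lists, highest other 10, 19 of 100 splits as large), Desipramine (7 and 8, 14 splits), Maltodextrin (8 and 9, 9 splits) or Probiotics (2 and 3, 58 splits).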

How the results depend on the processing

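Tests without ILC and LConly, with only 5 regions, without the 4 smallest libraries and with the axis covariate were chosen after the data were seen. Where a value below moved or turned, the cause was not tested, except that fewer regions give lower sums by construction.

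The all-region counts stayed within 1.5 times their value under each setting tried: 8086 to 10492 for FT, 7096 to 10469 for Bupropion, 8690 to 11586 for Desipramine, 7233 to 9319 for Probiotics and 5628 to 9179 for Maltodextrin. Leaving out replicates gave 9200 to 10294, 8555 to 8837, 10583 to 10794, 8328 to 8525 and 6981 to 7447 in the same order, and for the sums over regions 62188 to 65715, 53095 to 54670, 63207 to 64522, 49172 to 49735 and 42941 to 45038. With 5 regions those sums were 29518, 28122, 34540, 23604 and 25965. The counts of genes whose group difference varied between regions, or that differed between treatments, stayed within 1.5 times as well. An estimated correlation gave 20 list calls over all regions against 36 with the preset one, and 137 against 345 in single regions. With split controls Probiotics and Maltodextrin shared 570 genes in direction, against 948. Svaseq's planned 7 surrogate variables in ILC could not be fitted. With fewer there, the counts changed with the number of processor threads, so ILC has no value with surrogate variables and no sum over regions is given for them.

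Same-numbered replicates of different treatments correlated at a median r of 0.104, over 0.1 in 38 of 75 pairs, against -0.027 and 58 of 300 pairs for different numbers, a hint of a shared effect of the number. Pairing asked for every pair over 0.1, and 4, 4, 2, 3 and 3 of the 5 pairs of FT, Bupropion, Desipramine, Probiotics and Maltodextrin were, so libraries were not treated as paired. With the replicate block the all-region counts were 9697, 9213, 10990, 8945 and 7818, with 35 list calls. The replicate block ended the calls of Bdnf in dorDG of FT (0.0513) and of the GABAergic list in Desipramine (0.0514) and gained Jup in Desipramine (0.0223).

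Counts of single regions moved by over 1.5 times in a few cases. Maltodextrin BLA went from 3625 to 5449 with no filter, and Maltodextrin dorDG from 128 to 61 with no filter, 1021 with only the groups compared, 610 with surrogate variables and 40 to 74 when replicates were left out. Bupropion dorDG went from 1941 to 4212 with only the groups compared and 3498 with surrogate variables. With only the groups compared Desipramine BLA went from 5722 to 3652 and Probiotics BLA from 2760 to 4326, and Probiotics BLA was 6439 against Control.

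Of the values of named genes, 3340 kept direction and side of the threshold under other settings, 52 lost their call, 32 gained one and 22 turned; leaving out replicates gave 3413, 48, 9 and 0, and 2 alternatives gave no adjusted p. Of list calls 127 held, 52 were lost and 1 turned under other settings, and 347 held and 13 were lost when replicates were left out. A prior count of 0.5 ended oligodendrocyte precursor in FT (0.0529) and Bupropion (0.0589) and preoptic in FT (0.0643).

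Log2 changes that turned with the other control group were Slc6a4 in Bupropion (0.14), Tph2 in Desipramine (0.11), and in Probiotics Eif4a2 in ILC (0.20), Slc6a4 (-0.46), Cxcl13 (-3.45), Fcnb (-3.66) and RT1-Db1 (-2.13). With limma on mean log2 CPM, Nts in FT (0.014) turned. Without ILC and LConly, Cryzl1 (0.10), Srsf5 (-0.0050) and Ntf3 (0.018) turned in Maltodextrin. With 5 regions, Fkbp5 (0.12) and Slc4a5 (-0.027) turned in FT, Cryzl1 (0.0020) in Bupropion, Syvn1 (-0.11) and Jup (-0.12) in Desipramine, and RT1-Db1 (-0.58) in Probiotics. In Maltodextrin, Cxcl13 (0.020), RT1-Da (0.18), Cryzl1 (0.11) and Fcgr3a (0.077) turned there, and the immediate early list pointed down (0.237). Mip turned in Desipramine with the axis covariate (-0.074). Depth limits values from Desipramine BLA replicate 3 most, at 198260 counts.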

Other observations

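Values here were chosen after they were seen, and no cause was tested. In mPOA of FT, Pomc was at 375 ± 112 CPM (mean ± SD, n = 5) against 2.37 to 9.95 CPM in mPOA of the other groups. There Npvf, which encodes the RFamide-related peptides, was at 127 ± 27.2 CPM in FT and at 0.136 ± 0.129 CPM in Control. Agrp, a peptide of neurons that drive feeding, was at 19.4 ± 4.63 CPM in FT and 0.708 ± 0.299 CPM in Control. Oxt in NACShell was at 213 ± 75.1 CPM in FT and at 0.734 to 5.39 CPM in the other groups.

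Glial and choroid plexus genes varied between groups of the same region. Ttr in LConly was at 16980 ± 602 CPM in Probiotics and 39.6 ± 3.61 CPM in Control. In venDG its mean was 9963 CPM in Control, 12980 in Maltodextrin, 737 in FT, 15850 in Bupropion, 6573 in Desipramine and 5773 in Probiotics. Mbp in BLA was at 61170 ± 13820 CPM in FT and at 12640 to 18560 CPM in the other groups. Gabra6, a gene of cerebellar granule cells, was at 65.0 ± 5.69 CPM in LConly of Probiotics and at 46.3 ± 6.62 CPM in the FT libraries labelled ILC.

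Lists were also tested in single regions with camera. With FT, myelin genes were higher in BLA, CGC and the libraries labelled ILC and lower in mPOA, PLC, Raphe, venDG and the libraries labelled LConly, and 6 of these calls held with an estimated correlation. Oligodendrocyte precursor genes were higher in 5 of 10 regions with Probiotics (0 with an estimated correlation), and excitatory neuron genes in BLA, CGC, PLC and Raphe (4 with an estimated correlation). Antigen presentation genes were lower in 8 regions with Desipramine, 5 with FT, 3 with Bupropion and 3 with Maltodextrin, and microglia genes in 6, 7, 2 and 5. With an estimated correlation these counts were 4, 3, 2 and 3 for antigen presentation and 1, 3, 1 and 1 for microglia genes.

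Across genes, which are not independent replicates, the median correlation of changes between pairs of regions was 0.365 for FT, 0.445 for Bupropion, 0.468 for Desipramine, 0.521 for Probiotics and 0.175 for Maltodextrin. Maltodextrin in ILC and Probiotics in dorDG correlated at r = -0.693, with 5795 of 6341 shared calls opposite in direction and 546 the same. The 18 other pairs that keep either of these and change the region of the other ran from -0.404 to 0.370. In the label check, Bupropion and Probiotics ILC each had 5 nearest to PLC, FT dorDG had 3 nearest to venDG, and Probiotics dorDG and Maltodextrin PLC each had 2 nearest to ILC.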
